A study of Mus musculus with 2 samples.

How the data were processed

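ATAC-seq was done on 1 library of AB22 mouse mesothelioma cells with an induced control hairpin (shCTRL) and 1 with an induced hairpin against Hmgb1 (shHMGB1). Per the labels, cells were infected with lentivirus at a multiplicity of 20, selected with 4 µg/mL puromycin, kept at 37 °C and 5% oxygen (as the label has it; 5% carbon dioxide may have been meant), induced with 1 µM doxycycline and used 7 to 10 days later. The groups were taken from the silencing label of each sample, and no sample was left unassigned. RNA-seq and break maps of the same study were not analysed here.

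Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.32, aligned with BWA 0.7.5-r404 to mm10 (GRCm38), and handled with SAMtools, bedtools and MACS2. Settings, read filters, any shift of reads for the transposase and the caller of the nucleosome-free regions were not given in the sources used here. The lists hold 1 set of peaks per library, in the deposited layout of MACS2 narrow peaks with several summits per peak. The deposited score of a peak is the whole part of 10 times its −log10 q. The deposited fold is a ratio of summit pileup to expected pileup, and the deposited −log10 p and −log10 q refer to the same summit within 1 library. For the nucleosome-free regions, the deposited columns 4 and 5 were read as fractions of nucleosome occupancy (mean, and lowest upper bound), and the other deposited value columns as signal, the densities of insertions and of the sequence bias. Those readings come from the layout and the value ranges, and were not stated by a header.

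From each list the fragments behind a summit were recovered. The folds advanced in steps of a single size, as (pileup + 1)/(expected + 1) gives with a single expected pileup for the library. All 180632 summits of shCTRL and all 156812 of shHMGB1 came out as whole numbers within 0.001, and the deposited −log10 p matched a Poisson tail with these values within 0.000126 at the 179830 and 155641 summits compared, those with a −log10 p under 200. The expected pileup of 2.79 and 1.68 fragments is a single scale per library and is called background here. It was not measured outside peaks, and it cannot be split into depth and background. A single background for the whole genome means that no local correction was made, so stretches with a raised background list more peaks. Because calls need a lower pileup in the library with the lower expected pileup, 7 against 10, numbers of peaks cannot be compared without regard to this scale.

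Rows of the same interval were merged, keeping the highest summit, on chromosomes 1 to 19, X and Y. Peaks were shared if they overlapped by at least 1 bp, and the overlap was set beside that after 20 random circular shifts. Shares have exact Clopper-Pearson 95% intervals and pileups exact Poisson 95% intervals. Ratios of pileups have conditional binomial intervals, taken relative to the median gene, and to the median of genes in the same decile of mean height over background. All of them cover counting error only, since fragments without molecular identifiers are not independent molecules and a single library has no replicate spread. No test between conditions was made.

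The gene table used (GRCm38.p6) gives gene starts and ends, without strand or exons. Promoters, exons and introns as first planned were therefore replaced by windows of 1 kb on either side of both annotated ends of 21887 coding genes, and by gene body and other sequence. An end can be the outer end of a rare transcript, so the main promoter of a gene can lie outside its window, and 1 of the added alternatives took the whole gene with 1 kb around it. Motif and base content of peaks needed the genome sequence, which was not used here. Summits at gene ends were matched within 150 bp. The 16 gene lists named 287 genes, of which 286 matched the table, and Mx1 did not. A list's counts or median were placed among 10000 random lists of the same size, matched on the number of libraries with a peak and on its height, with ties split evenly in percentiles, and the medians also over distinct summits, a choice made after the data were seen. For nucleosome-free regions the share of draws at least as far off is given, ties included.

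The gene lists, thresholds, sharing rules, alternatives and rule for named genes were fixed before the data were examined. The rule named Hmgb1, list members with an end peak in exactly 1 library, up to 3 members per list with the highest deposited fold in shCTRL among those open in both, the 12 coding genes per library with the highest deposited fold among end peaks without a counterpart, and the 3 strongest such peaks elsewhere, leaving out genes named Gm with a number or ending in Rik, but not those with LOC identifiers. Genes named for other reasons, among them members with no peak and the 10 genes per direction farthest from the median ratio with a combined pileup of at least 60, were chosen after their values were seen. So were the windows with many weak peaks (the top 5% of 1 Mb windows by peaks with a −log10 q under 5), the peak-free stretches and the random draws for nucleosome-free regions. A few genes that the rule would name, and 1 covered block, are not reported here; they stay in the counts.

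Alternatives were a −log10 q of at least 5 or 10, equal numbers of peaks, autosomes only, a reciprocal overlap of 50%, summits inside peaks, gene-end windows of 500 bp or of 2 kb outside and 500 bp inside, regions in peaks of both libraries, regions of at least 50 bp, and scaling to the median matched peak. Added after seeing the data were thinning of shCTRL pileups to the shHMGB1 background, leaving out the windows with many weak peaks, whole genes, ratios relative to genes of the same height, windows chosen on shHMGB1 alone, insertion density over background, and the alternatives of the break repair count. The functions were tested on simulated data: over 20000 simulated peaks all pileups were recovered, 50% were found shared as planted, all 2000 planted gene ends were found, and, at a mean pileup of at least 40, all 23 peaks raised 4-fold and all 20 lowered 4-fold had intervals off the median of the unchanged peaks, as had 3.61% of 1941 unchanged ones. In the real lists the reference was the median of all matched genes. Recovery of smaller changes, or of changes at lower pileups, was not assessed. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.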

Results

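Open chromatin was mapped by ATAC-seq, in which the transposase Tn5 cuts accessible DNA and leaves sequencing adapters, in AB22 cells, a mouse malignant mesothelioma line. The cells carried a doxycycline-inducible short hairpin RNA, either a control hairpin (shCTRL) or a hairpin against Hmgb1 (shHMGB1), whose product HMGB1 is an abundant chromatin protein that bends DNA. Each condition had 1 library, so no difference between the 2 lines could be set against a spread between replicates, and no p-values are given for it. The comparison addressed how loss of HMGB1 alters nucleosomes, in a study of breaks made by irradiation; no irradiation dose was given for these libraries. The deposited lists held 104336 peaks for shCTRL and 92282 for shHMGB1, and 16275 and 14634 nucleosome-free regions. Read totals were not given in the sources used here. The expected pileup per position recovered from the lists, called background here, was 2.79 fragments in shCTRL and 1.68 in shHMGB1, a ratio of 0.603. The lowest summit pileup listed was 10 and 7. Heights over background are therefore scaled by library, and are not a measured ratio of signal to noise. All positions refer to mm10 (GRCm38) and count from 1, and all intervals given with pileups or shares cover counting error only. Intervals of a median take peaks or regions as independent. Neither they nor the bootstrap interval hold any spread between libraries.

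The silenced gene itself was open in both libraries. Hmgb1 (gene 15289, chromosome 5, 149046702 to 149053057) carried a peak over its higher-coordinate end, from 149052228 to 149053659 in shCTRL and from 149052708 to 149053528 in shHMGB1. Its summit pileup was 75 fragments (95% Poisson interval 59.0 to 94.0) in shCTRL and 83 (66.1 to 102.9) in shHMGB1, or 26.8 and 49.3 times the background of each library. Set against the median of all coding genes with matched summits, the log2 ratio of shHMGB1 over shCTRL was 0.33 (95% interval -0.14 to 0.80). A hairpin acts on the RNA, so accessibility of the gene does not check the labels.

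Strong open sites were nearly all shared by both lines, and the lists differed at weak ones. Of the 104336 shCTRL peaks 60.1% (exact 95% interval 59.8 to 60.4) overlapped a shHMGB1 peak, and of the 92282 shHMGB1 peaks 69.0% (68.7 to 69.3) overlapped a shCTRL peak, against 2.33% and 2.49% when a list was shifted along each chromosome. Among peaks with a deposited −log10 q of 20 or more, 3 of 18596 in shCTRL and 15 of 20445 in shHMGB1 had no counterpart. Below a −log10 q of 5 the shared part was 31.9% (31.5 to 32.3) and 41.2% (40.7 to 41.7). Peaks without a counterpart had a median pileup of 12 in shCTRL and 9 in shHMGB1, near the lowest that was listed. The order of the peak numbers depended on the threshold: with a −log10 q of at least 10, shCTRL held 30783 peaks and shHMGB1 32327.

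**Figure D1:**
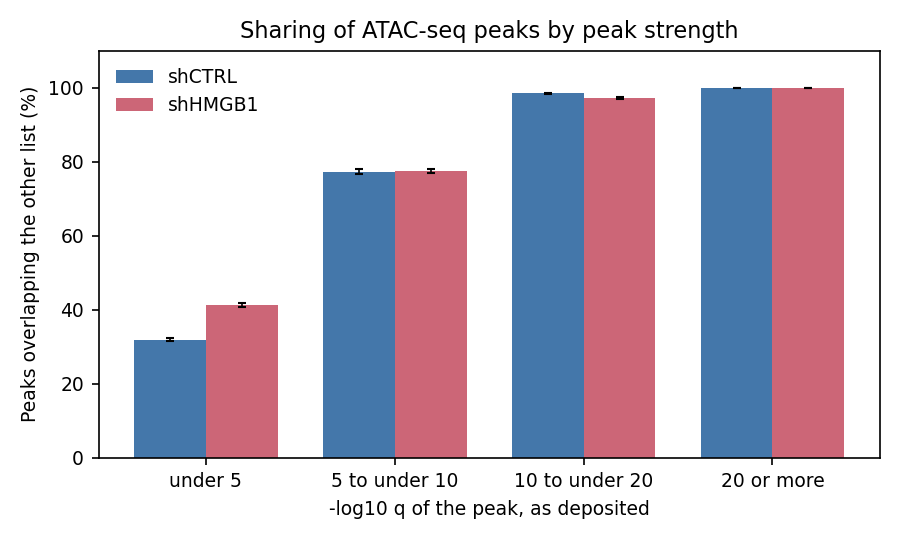
Share of peaks (y axis, percent) of the shCTRL and the shHMGB1 list that overlap the other list by at least 1 bp, by the deposited −log10 q of the peak (x axis); bars show 1 library each and error bars exact 95% binomial intervals (counting error only). The shares run from 31.9% and 41.2% in the weakest class to nearly all peaks in the strongest.

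The excess of shCTRL peaks was uneven over the genome. Of 21 chromosomes 13 held more peaks in shCTRL. Chromosome 2 held 15273 peaks in shCTRL and 9794 in shHMGB1, chromosome 4 held 12599 and 9232, chromosome 15 held 5762 and 4360 and chromosome 19 held 4185 and 3254, while others, such as chromosomes 3 (4471 and 5086), 13 (2691 and 3220) and X (1445 and 1777), held fewer in shCTRL than in shHMGB1. The 120 windows of 1 Mb with the most weak peaks, of 2401 windows in all, lay on 14 chromosomes, with 34 on chromosome 2, 21 on chromosome 4 and 13 on chromosome 17. In them shCTRL had 31713 peaks and shHMGB1 17793, a ratio of 1.78. In the other 2281 windows the counts were 72623 and 74489, a ratio of 0.975. These windows were chosen after the data were seen and held 50.7% of the shCTRL peaks without a counterpart, against 20.6% of such shHMGB1 peaks. Most peaks without a counterpart were weak, so these values partly follow from the choice. In 120 windows chosen on the weak peaks of shHMGB1 alone the ratio was 1.70, and 0.992 elsewhere, and the shares were 48.1% and 21.0%.

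**Figure D2:**
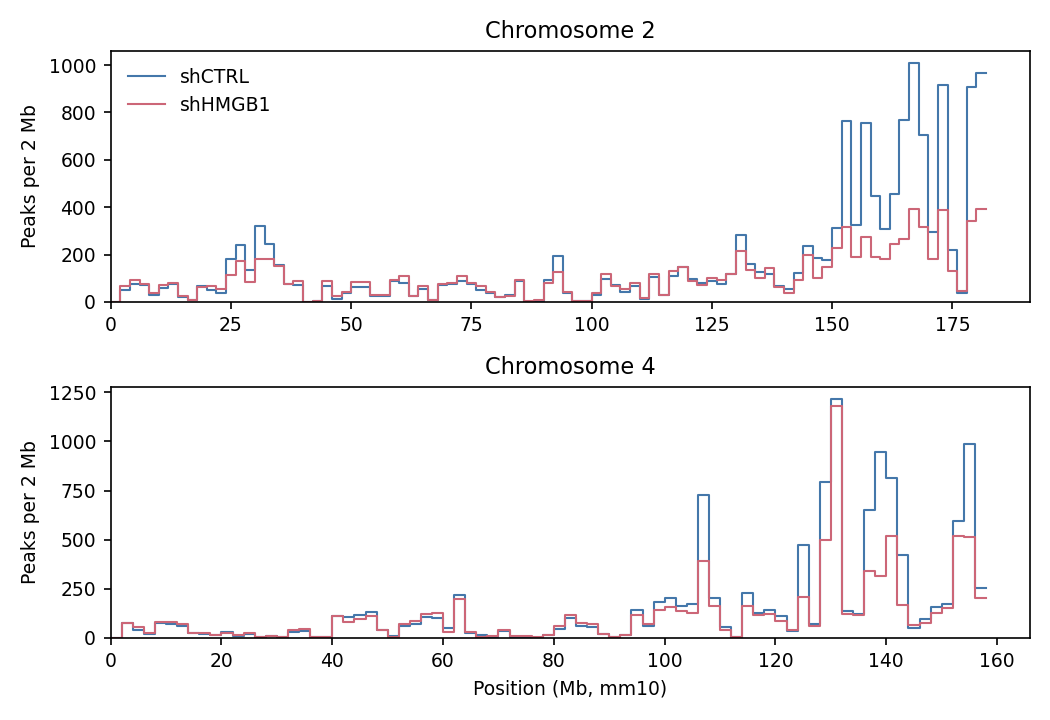
Peaks per 2 Mb window (y axis) along chromosomes 2 and 4 (x axis, position in Mb) in the shCTRL and the shHMGB1 library. The distal part of chromosome 2 and several blocks of chromosome 4 show the widest gaps between the libraries, whose totals are 15273 and 9794 peaks on chromosome 2 and 12599 and 9232 on chromosome 4.

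The most enriched peaks of 1 list at coding gene ends were modest in height. In shCTRL they lay at Zfp518a (chromosome 19, 40894493 to 40895178, pileup 28, interval 18.6 to 40.5), Nol4l (27), the phosphodiesterase gene Pde3a (26), and Prh1, the semaphorin gene Sema3f and Vxn (25 each). They were followed by Dock10 (24), a gene for an exchange factor of small GTPases, and, at 23 each, by the adenylate cyclase gene Adcy8, Insm1, Klf16, LOC100504180 and Macrod1. In shHMGB1 they included those at Smim15 (chromosome 13, 108043465 to 108043732, pileup 27, interval 17.8 to 39.3), at the acute-phase protein gene Orm2 (25), and at Il18rap, the Rac activator gene Tiam1 and Tmem19 (20 each). At B3galt6, Dynlt1c, Ghitm, Mtmr2, Ptrh2 and Zfp882 the pileup was 19 each. Most of the genes picked in this way, 8 of 12 in each library, such as Zfp518a, Sema3f, Smim15 and Ghitm, had another end peak in the other library too. A pileup below the listing limit of the other library was not given, so no fold was formed at these sites. Set against the highest pileup under that limit, and if all sites above it were listed, the fold over background would be at least 2.81 at Zfp518a and 4.97 at Smim15, before counting error.

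Away from gene ends, the strongest peaks of shCTRL alone lay within Lama2 (chromosome 10, 27378327 to 27378524, pileup 35, interval 24.4 to 48.7), which encodes a laminin chain, at 5697 bp from Nppa (33) and in a gene-poor stretch of chromosome 9 with Arpp21 as nearest gene, at 554119 bp (32). Those of shHMGB1 alone had Pex2 (chromosome 3, 6049547 to 6049942, pileup 41, interval 29.4 to 55.6), Htra3 (32) and Cyp2b10 (31) as nearest coding genes, at 470951, 17608 and 20750 bp.

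Gene ends took the same part of the 2 full lists, but a larger part of the shCTRL list when the lists were cut to stronger or to equally many peaks. Within 1 kb of an annotated end of a coding gene lay 17.6% of the shCTRL peaks (17.4 to 17.8) and 17.6% of the shHMGB1 peaks (17.4 to 17.9), gene bodies held 45.1% and 42.7%, and 37.3% and 39.7% lay outside coding genes. Among peaks without a counterpart, gene ends made up 12.6% (12.2 to 12.9) in shCTRL and 8.57% (8.25 to 8.91) in shHMGB1. Among peaks with a −log10 q of at least 10 they made up 28.9% (28.4 to 29.4) and 26.7% (26.2 to 27.2), and with equal numbers of peaks 18.4% and 17.6%.

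Of 21887 coding genes, 11532 had an end peak in both libraries, 1226 in shCTRL alone, 375 in shHMGB1 alone and 8754 in neither. The last count includes genes that the annotation places at the very start of chromosome 1, such as Csprs (from 111558) and Ren2 (from 159748). Whether a peak could be listed at such positions was not checked. The top peaks of the genes seen in 1 library had a median pileup of 13 in shCTRL and 9 in shHMGB1, against 44 and 38 for genes open in both. With a −log10 q of at least 5 the shCTRL count was 642 and the shHMGB1 count 340. Among the members of the 16 gene lists, a peak in a single library was always low, with pileups of 10 to 18 in shCTRL and 8 to 11 in shHMGB1.

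Genes for chromatin proteins were open in both lines. Here and below, the leading members of a list are those highest in shCTRL. Pairs of pileups printed with a log2 ratio are of matched summits. Other pairs are of the highest end peak of each library, which can lie at different sites. All 10 genes of the HMG family had end peaks in both, led by Hmgb2 (pileup 225, interval 196.6 to 256.4, in shCTRL and 262, 231.2 to 295.7, in shHMGB1), the close relative of Hmgb1, and by Hmgn5 (134 and 144) and the histone chaperone gene Ssrp1 (112 and 107). Relative to the median gene, Hmgb2 stood at a log2 ratio of 0.40 (0.14 to 0.66), but relative to genes of its own height at 0.20 (-0.07 to 0.46), which includes no difference. Of 67 replication-dependent and linker histone genes 57 were open in both, with H2ac22 and H2bc22 sharing a peak (61 and 51) and H2ac12 next (57 and 52) in shCTRL. The linker gene H1f10 was seen in shCTRL alone (15) and H3c14 in shHMGB1 alone (8), while H4c12, H2bc23, H2ac23 and H4c17, together with H1f6, H2bc1, H2ac1 and H1f7, had none. The histone genes stood at a median log2 ratio of 0.12 relative to all genes, at percentile 99.9 of 10000 random lists matched on height, with 6 intervals above 0 and 0 below. Their 57 genes rested on 42 distinct summits, over which the median was 0.10, at percentile 99.5 of random lists of distinct summits, with 4 intervals above 0, and reads from near-identical copies cannot be assigned with certainty. Most of these genes lie close together on chromosomes 13 and 3, while the random lists were not matched on position. A shift of a whole region would move such neighbours together, so the percentiles are not those of independent genes. Histone variants and assembly factors were open in both for 23 of 24 genes, led by the remodeller gene Smarca2 (232 and 206), the chaperone gene Asf1a (173 and 167) and H2az1 (158 and 136), and their median of 0.08 stood at percentile 55.3. Atrx (17 and 32; 1.09, 0.20 to 2.03) and Srcap (42 and 62; 0.74, 0.15 to 1.34) stood above the median gene, and also above genes of their height, at 1.21 (0.32 to 2.15) and 0.74 (0.15 to 1.34). Atrx lies on chromosome X, which held fewer peaks in shCTRL than in shHMGB1 (1445 and 1777). Its ratio was not set against that of its neighbours, so a shift of the whole chromosome was not told apart from a change at Atrx. The same holds for Pgk1, below.

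Genes that respond to DNA breaks and drive the cell cycle were also open in both. Of 25 genes for sensing and repair of double-strand breaks 23 had end peaks in both, led by Atm (152 and 114), which encodes the kinase that senses breaks, Xrcc4 (133 and 155) and Dclre1c (121 and 108), both of non-homologous end joining. Xrcc6, which encodes the end-binding protein Ku70, had an end peak in shCTRL alone (17, interval 9.9 to 27.2), and Rbbp8 had a peak within the gene but none at its ends. The median log2 ratio of the list was 0.10, at percentile 82.3, and Xrcc4 stood at 0.40 (0.06 to 0.75), or 0.20 (-0.15 to 0.54) relative to genes of its height. Atm stood at -0.23 (-0.60 to 0.13), and relative to its height at -0.44 (-0.80 to -0.08). Of 19 genes of the p53 pathway 17 were open in both, with Ccng1 (173 and 223; log2 ratio 0.55, 0.25 to 0.84) and the stress gene Gadd45a (156 and 199; 0.53, 0.22 to 0.84) above the median gene, Trp53 (50 and 26; -0.76, -1.51 to -0.05, although its highest shHMGB1 peak held 42) and Sesn1 (42 and 21; -0.82, -1.65 to -0.03) below it and Trp53inp1 (75 and 81) with an interval that included it. Relative to genes of the same height these were 0.34 (0.05 to 0.64), 0.33 (0.02 to 0.64), -0.73 (-1.47 to -0.02) and, including no difference, -0.69 (-1.52 to 0.10). Cdkn1a had peaks inside the gene only and Perp had none, and the list median was 0.07, at percentile 70.8. All 21 cell cycle and replication genes were open in both, led by the cyclin gene Ccna2 (145 and 126), Mcm3 (144 and 172; 0.44, 0.11 to 0.77, but 0.23, -0.09 to 0.56, relative to its height) and the mitotic kinase gene Aurka (128 and 99), with a median of 0.07 at percentile 51.1. Relative to their height Aurka stood at -0.39 (-0.79 to -0.004) and Ccne1 at -0.42 (-0.84 to -0.003), both of which included no difference relative to the median gene.

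Most mesothelial marker genes lacked an end peak in both libraries at once, and most mesenchymal genes had one. Of 12 mesothelial markers, Msln (22, interval 13.8 to 33.3, and 12, 6.2 to 21.0), which encodes mesothelin, and Pdpn (16 and 13) had end peaks in both. Krt19 (13), Wt1 (12) and Calb2 (13) had one in shCTRL alone, Lrrn4 (9) in shHMGB1 alone, and Krt8, Krt18, Upk1b, Upk3b, Gpm6a and Muc16 had no peak in the gene or within 1 kb in either. Of 16 mesenchymal genes 13 were open in both, among them the repressor gene Snai1 (105 and 67), the smooth muscle actin gene Acta2 (95 and 80) and S100a4 (92 and 97), while Itga5, Cdh2 and Tagln had no end peak. Snai1 stood below the median gene, at a log2 ratio of -0.47 (-0.93 to -0.01), and the list median of -0.07 lay at percentile 23.7. Tumour suppressor and Hippo pathway genes were open in both for 14 of 16, led by the Hippo kinase gene Stk3 (141 and 69), Ankrd1 (81 and 66) and Wwtr1 (74 and 68), and Cdkn2a and Cdkn2b had no peak. Stk3 stood at -0.85 (-1.29 to -0.43), and the list median of 0.02 at percentile 56.9.

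Of 25 inflammatory and interferon response genes found in the annotation 17 were open in both, led by Stat2 (71 and 65) and Ifit2 (65 and 66), while Tlr4 was highest in shHMGB1 (49 and 87). The 87 fragments were not at the matched summit of Tlr4. There the log2 ratio relative to the median gene was 0.24 (-0.36 to 0.83), which includes no difference. The chemokine receptor gene Cxcr4 had an end peak in shCTRL alone (10), and Ccl5, Ager, Tnf, Il1b, Ifnb1, Cxcl2 and Oas1a had none. The list median of 0.09 stood at percentile 91.8, with Nfkbia (45 and 61; 0.62, 0.04 to 1.21) above the median gene and, relative to height, Cxcl1 too (1.00, 0.04 to 1.99). Of 15 housekeeping genes 14 were open in both, led by Eef1a1 (130 and 139), Gapdh (111 and 108) and Actb (90 and 77), with Pgk1 (84 and 103) above Actb in shHMGB1 and a median of 0.05 at percentile 54.4. Of these control genes, Tubb5 (34 and 54; 0.85, 0.20 to 1.51) and Pgk1 (0.47, 0.04 to 0.91) stood above the median gene and Gusb (62 and 32; -0.77, -1.44 to -0.14) below it, and Tubb5 and Gusb also relative to height, at 0.84 (0.20 to 1.51) and -0.78 (-1.44 to -0.14). So control genes strayed as well, as far as Trp53, Ccng1 or Snai1. Ywhaz had a peak within the gene only.

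Of 21 markers of leukocytes, epithelium and endothelium 2 had an end peak in both libraries and 9 in at least 1, while of the 21887 coding genes 11532 had one in both and 8754 in neither. The end peaks of these markers had pileups of 10 to 18 in shCTRL and 10 or 11 in shHMGB1. The lowest listed pileup was 10 and 7, and the median listed peak had 15 and 13. Several fibroblast markers and a neuronal one were higher. Of 9 fibroblast markers 5 were open in both, with the collagen genes Col1a2 (74 and 77), Col3a1 (27 and 20) and Col1a1 (27 and 18) leading, and Pdgfra (9) in shHMGB1 alone. Of 9 leukocyte markers Spi1 (14 and 10) was open in both, Csf1r (18) and Cd68 (14) in shCTRL alone and Lyz2 (11) in shHMGB1 alone, and Ptprc in neither. Among 7 epithelial markers Krt14 (13 and 10) was open in both and Esrp1 (16) and Grhl2 (10) in shCTRL alone, with none at Epcam or Cdh1. Among 5 endothelial markers Tek (13) and Cdh5 (11) were open in shCTRL alone and none in both. Among 6 neuronal markers Snap25 (47 and 30) was open in both and Grin1 (15) in shCTRL alone. These peaks of Snap25 did not overlap, at 136712154 to 136712683 in shCTRL and 136713194 to 136714429 in shHMGB1. Its matched summits stood at a log2 ratio of -0.12 (-0.87 to 0.61) relative to the median gene. For each of the 9 lists with a member open in a single library, the difference of these counts lay between percentiles 25.4 and 92.8 of 10000 random lists matched on height.

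Open sites stood higher over background in shHMGB1. At 52099 peaks that each overlapped a single peak of the other list, the summit pileup over the background of its library was higher in shHMGB1 by a median log2 ratio of 0.52 (95% interval of the median 0.51 to 0.52), or 1.43-fold, with quartiles of 0.20 and 0.82. The ratio was 0.20 where the mean height was under 5 times background, 0.63 from 10 to under 20, and 0.78 (0.76 to 0.79) from 40 upward. In the weakest class it is partly set by the listing limits, since the lowest heights listed were 3.58 times background in shCTRL and 4.15 in shHMGB1. Height was also the mean of the 2 values compared. The pileups themselves, not divided by background, had medians of 21 in shCTRL and 18 in shHMGB1, a median log2 ratio of -0.21, so the direction rests on that scaling. At coding gene ends, 10991 genes had matched summits with a median log2 ratio of 0.55, and the interval of 916 genes (8.33%) excluded that median, 607 above it and 309 below, while 34 genes stood at least 2-fold above it and 187 at least 2-fold below. The ratio went with height, which at low heights can come in part from the listing limits. Relative to genes in the same decile of height, the interval of 564 genes (5.13%) excluded no difference, 287 above and 277 below, and 69 and 78 stood at least 2-fold off. Of exact 95% intervals up to 5% miss an unchanged value by design, so an interval that barely excludes no difference sets no gene apart.

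**Figure D3:**
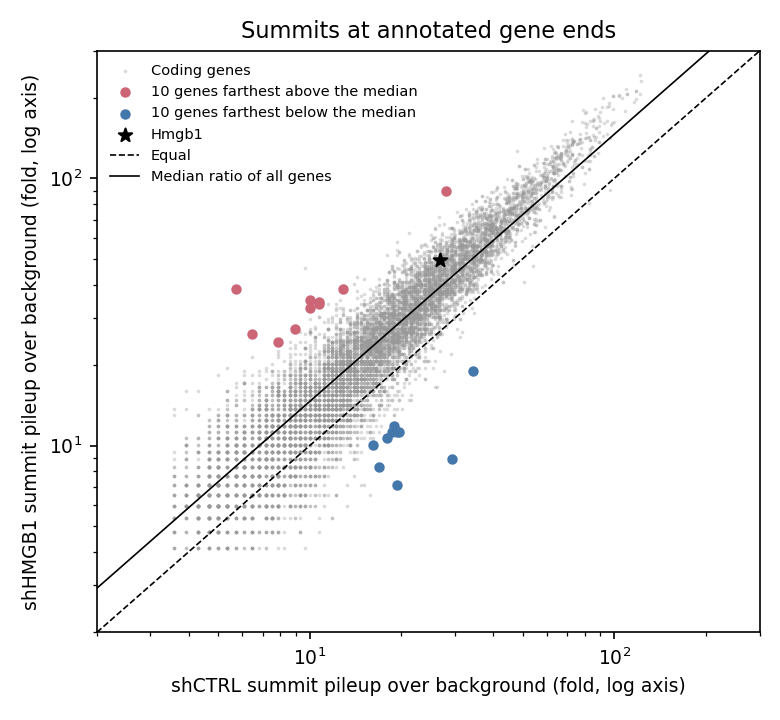
Summit pileup over the background of the library (fold, log axes) in shCTRL (x axis) and shHMGB1 (y axis) at the annotated ends of 10991 coding genes, 1 library per condition. The solid line marks the median log2 ratio of 0.55, the dashed line equality, and the star Hmgb1 at 26.8 and 49.3. Coloured points are the 10 genes farthest above and the 10 farthest below the median among the 7100 with a combined pileup of at least 60.

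The listed nucleosome-free regions of shHMGB1 had a slightly lower median occupancy, and a slightly larger median width that matched regions did not show. The median region was 159 bp wide in shCTRL (95% interval 157 to 160) and 166 bp in shHMGB1 (164 to 168), and the median estimated nucleosome occupancy was 0.0592 (0.0587 to 0.0598) and 0.0539 (0.0532 to 0.0545). The lists end at a ceiling of occupancy, with a highest mean of 0.09998 in shCTRL, so similar values are partly set by the call, and sites that gained nucleosomes would not be listed. The upper bound of occupancy ended too, at 0.24995 in shCTRL and 0.24999 in shHMGB1. Such a limit can act differently in libraries of unequal depth. Whether it had a part in the lower occupancy of shHMGB1 was not tested. Gene ends held 43.5% (42.8 to 44.3) and 42.5% (41.7 to 43.3) of the regions. Of the shCTRL regions 39.6% (38.8 to 40.3) overlapped a shHMGB1 region, and of the shHMGB1 regions 43.8% (43.0 to 44.6) a shCTRL region, against 0.214% and 0.235% after shifting. From the lowest to the highest quartile of insertion density this share went from 12.7% to 69.2% in shCTRL and from 19.7% to 66.2% in shHMGB1. At 6194 regions matched singly, occupancy was lower in shHMGB1 in 58.0% (56.8 to 59.3), with a median difference of -0.0054 (95% interval of the median -0.0063 to -0.0045, quartiles -0.0258 and 0.0141), and the median width differed by 1 bp (-1 to 2, quartiles -25 and 29 bp). Insertion density was lower in shHMGB1 in 65.7% (64.5 to 66.8), by a median log2 ratio of -0.13 (-0.14 to -0.12), without scaling for depth. Divided by the background pileup of each library, as for peaks, it was higher in shHMGB1, at 0.60 (0.59 to 0.61), so the direction rests on that scaling here too.

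**Figure D4:**
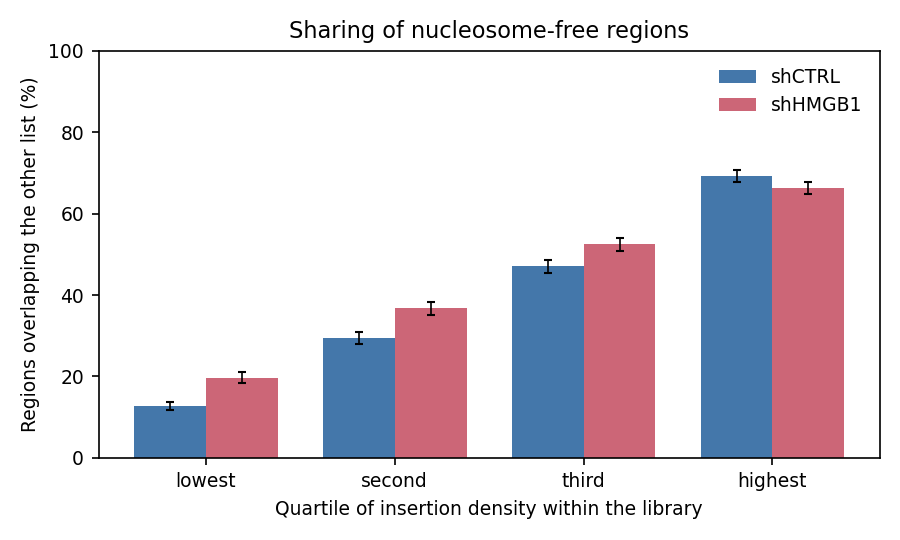
Share of nucleosome-free regions (y axis, percent) of each library that overlap a region of the other library by at least 1 bp, by quartile of insertion density within the library (x axis); error bars are exact 95% binomial intervals (counting error only). The shares climb from 12.7% and 19.7% in the lowest quartile to 69.2% and 66.2% in the highest.

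Among the break repair genes, the nucleosome-free regions seen at gene ends in a single library were all in shCTRL. At Hmgb1 a region lay over the same end in both, from 149053003 to 149053234 (232 bp) in shCTRL and from 149052999 to 149053269 (271 bp) in shHMGB1. Of the 25 double-strand break genes, 12 had a region in both, among them Atm, Brca1, Nbn, Mre11a, Prkdc, Xrcc4 and Parp1, 8 in shCTRL alone and 0 in shHMGB1 alone. Here and below, a gene counted in both had a region at either end in each library, and these can lie at different sites. At Prkdc, for example, a shCTRL region ran from 15637527 to 15637611 and a shHMGB1 region from 15637753 to 15637962, without overlap. Prkdc had 2 regions in shCTRL and 3 in shHMGB1. Among the 8 were the checkpoint kinase genes Atr, Chek1 and Chek2, the recombination gene Brca2, and Rad50, Nhej1 and Trp53bp1. At Chek2 the shCTRL region ran from 110839696 to 110839999 on chromosome 5 (304 bp, occupancy 0.0286), at Brca2 from 150522534 to 150522638 (105 bp, 0.0103) and at Atr, on chromosome 9, from 95857437 to 95857676 (240 bp, 0.0925). Of 10000 random draws from genes with a region in a single library 1.36% gave all 8 in shCTRL, the lowest share of 12 lists placed in this way after the counts were seen, and all 8 genes had an end peak in both libraries. In the p53 list, 11 genes had a region in both and Trp53, Zmat3 and Sesn2 in shCTRL alone (20.2% of draws). In the cell cycle list, 13 had one in both and Mcm3 and Pcna in shHMGB1 alone (17.7% of draws). The histone list had 3, 13 and 10 (H2ac20, H2ac21 and H4c14 in both), the HMG list 5, 2 and 2, and the list of histone variants and assembly factors 13, 4 and 1, in both, in shCTRL alone and in shHMGB1 alone. The Hippo list had 5, 0 and 2, with Lats2 and Ankrd1 in shHMGB1 alone, the mesenchymal list 8, 0 and 1, the inflammatory list 4, 4 and 2, and the housekeeping list 4, 2 and 2. Fibroblast genes had 0, 2 and 0 (Col1a2 and Thy1), leukocyte genes 0, 0 and 1 (Lyz2), neuronal genes 1, 0 and 0 (Snap25), and mesothelial, epithelial and endothelial genes none.

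Over all coding genes 4084 had such a region in both libraries, 2087 in shCTRL alone and 1468 in shHMGB1 alone. All 4084 belonged to the 11532 genes with an end peak in both, among which independent lists would share 2953.

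The locus of Cdkn2a, a tumour suppressor gene often lost in mesothelioma, had no peak in either list. On chromosome 4 the stretch from 88641230 to 90996964 (2.36 Mb) held none of the 104336 and 92282 peaks and 0 nucleosome-free regions, over Klhl9, Mtap, Cdkn2a, Cdkn2b, Dmrta1, Zfp352 and the type I interferon genes. The last peak before it ended at 88641229 in both, with pileups of 74 and 58. The first after it began at 91374555 in shCTRL (14) and at 90996965 in shHMGB1 (8). Stretches without peaks also covered broadly used genes: Canx and Hnrnph1 on chromosome 11 (50292834 to 50827262), Hint1 on chromosome 11 (54523296 to 55033082), and Rnf20 and Mrpl50 on chromosome 4 (48898992 to 49688757). These 3 stretches held 0 nucleosome-free regions too. The numbers in the peak names ran without a gap, to 104336 and 92282, which argues against peak rows left out after numbering. Whether a filter before numbering, or rows left out of the region lists, had a part in any of these stretches was not tested.

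**Figure D5:**
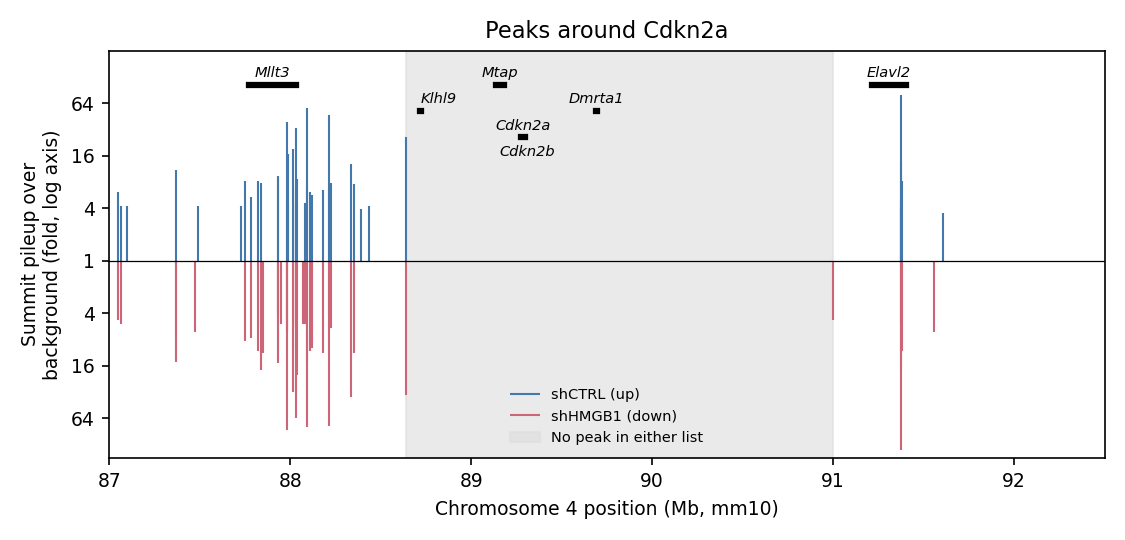
Peaks on chromosome 4 around Cdkn2a (x axis, position in Mb), each drawn as a line whose length is its summit pileup over the background of its library (fold, log axis), upward for shCTRL and downward for shHMGB1; black bars are genes. No peak of either library lies in the shaded 2.36 Mb.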

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

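Thinning of shCTRL, leaving out windows with many weak peaks, whole-gene windows, ratios relative to genes of the same height and the alternatives of the break repair count were chosen after the data were seen. No paired analysis was possible because each condition had 1 library, and leaving out a replicate was not possible for the same reason. The motif and base content result, with its 100 bp windows, was not run without the genome sequence. Of the alternative values of results that answer a comparison, 55 stayed within their interval or within 1.5 times the count and 34 did not, as follows, shCTRL before shHMGB1. The cause was not tested except where the alternative itself drops weak peaks or narrows a window.

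With a −log10 q of at least 5, the lists held 49868 and 51661 peaks, 80.8% and 78.2% were shared, gene ends made up 23.0% and 21.7%, and 642 genes had an end peak in shCTRL alone. With at least 10 these were 30783 and 32327 peaks, 86.7% and 82.3%, 28.9% and 26.7%, and 686 genes. The order of the peak numbers turned at both thresholds, and also without the windows of many weak peaks, at 72623 and 74489, and with shCTRL thinned, which only removes shCTRL peaks, at 86885 and 92282. The shared part was 65.3% and 66.7% with equal numbers of peaks, 66.5% and 64.4% with shCTRL thinned, 71.7% and 69.5% without the weak-peak windows, 43.1% and 48.8% with a reciprocal overlap of 50%, 54.5% and 63.1% by summits inside peaks, and 59.7% for shCTRL on autosomes. The part at gene ends was 18.4% in shCTRL with equal numbers, 18.7% with thinning, and 12.2% and 12.3% with windows of 500 bp. Of the nucleosome-free regions 33.1% and 36.8% were shared with a reciprocal overlap of 50%, and 41.7% and 45.2% within peaks of both libraries. Scaling to the median matched peak sets its own log2 ratio to 0 by construction, in place of 0.52.

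Genes with an end peak in both libraries numbered between 9055 and 14197 over all alternatives. The occupancy difference at matched regions kept its sign, at -0.0062 with a reciprocal overlap and -0.0054 within peaks of both. Of the break repair genes, 6 had a nucleosome-free region in shCTRL alone within 500 bp of an end and 8 under the 2 other alternatives, with 0 in shHMGB1 alone in each. Those 2 alternatives had little room to lower the count. The regions given for these 8 genes were 105 to 308 bp wide, and all 8 genes had an end peak in both libraries. Genes whose ratio interval lay above the median went from 607 to 287 relative to genes of the same height, and those below it from 309 to 277. The 2.79 and 1.68 fragments of background limit what a weak peak can show: a site listed in 1 library only is not shown to be closed in the other.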

Other observations

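The tests of copy number, of HMGB1 silencing and of windows chosen on shHMGB1 alone were chosen only after the results were seen, and the genes and regions named here were also chosen then. Among 7100 coding genes with a combined pileup of at least 60 fragments, 15 stood at least 2-fold above the median ratio of shHMGB1 over shCTRL and 31 at least 2-fold below. The farthest above were Tmem91 (pileup 16 in shCTRL and 65 in shHMGB1, relative log2 ratio 2.20, interval 1.40 to 3.09), Fbxo40 (18 and 44, 1.47), the steroid reductase gene Srd5a3 (28 and 59, 1.26), Rgs17 (28 and 55, 2.23-fold) and the apolipoprotein gene Apoa2 (78 and 151, 1.13). Defb47, Zfp799, the mitochondrial ribosome gene Mrpl52, Klk10 and the ferredoxin reductase gene Fdxr followed, at 1.13, 1.11, 1.08, 1.06 and 1.03. The farthest below were Slc22a29 (82 and 15, -2.27, -3.17 to -1.47), the calcium channel gene Cacna2d2 (54 and 12, -1.99), Hnrnpu (47 and 14, -1.57), Taco1 (96 and 32, -1.40) and Pcbp4 (55 and 19, -1.35), then Frg1, the histone demethylase gene Kdm3b, Cd244a, Lrrc75a and Sdc3, at -1.33, -1.29, -1.27, -1.23 and -1.22. Each rests on a single library per line.

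Some blocks were covered by peaks over much of their length in both lines. One of 120 kb on chromosome 1 (88200001 to 88320000), over the Ugt1a cluster, Mroh2a, Hjurp and Trpm8, was covered to 74.1% of the sequence in shCTRL and 68.7% in shHMGB1. Others, at Itln1 and Cd244a on chromosome 1, at Nphp4 on chromosome 4 and at Ccnl2 and Dvl1 on chromosome 4, measured 80 kb each and were covered to 55.5% and 50.4%, 75.8% and 40.3%, and 69.6% and 41.1%. Of the genes with a low ratio, Cd244a lay in such a block, and Sdc3 in another that is not described here. The strongest site of both lists lay on chromosome 1 from 24612257 in shCTRL, with pileups of 7785 and 9939, followed by sites on chromosome 2 at 98666172 (5300 and 5706) and chromosome 9 at 35305143 (2179 and 2299). The first stood at 2787 and 5899 times background. Such sites were not screened for reads misplaced from repeated sequence, so they are not shown to be the most accessible.

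The peaks of shCTRL without a counterpart were concentrated in windows with many weak peaks, most often on chromosomes 2 and 4, and the design gives no biological explanation for a regional pattern beyond the hairpin itself. A higher copy number of these windows in the shCTRL line might add such peaks, and would lower the ratio of strong summits there: strong matched summits in these windows stood lower than elsewhere by a log2 difference of -0.13 (bootstrap interval -0.15 to -0.11), short of the drop that was asked for, with an interval reaching the -0.15 set as the smallest drop that keeps it open. Depth alone might also add them, since a raised background would pass the listing limit sooner in a deeper library. After thinning shCTRL to the shHMGB1 background the ratio of peaks there was 1.37 (1.346 to 1.399), above what was set for depth alone and with an interval that reached the bound set to exclude it, against 0.839 in other windows. In windows chosen on shHMGB1 alone it was 1.31. The value of 1.37 itself lay past that bound, and its interval, which keeps depth open, was added after the value was seen. Neither could be told apart from the other on these values, and both may act together.

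Matched summits stood higher over background in shHMGB1. A single scale of signal over background between the libraries, such as a cleaner tagmentation, would shift strong sites alike, and the background-subtracted median log2 ratios of the 3 strongest classes spanned 0.11 (0.68 to 0.79), below the 0.20 set as limit, which is consistent with such a scale among strong sites. They rose from class to class with intervals apart, so an exact single scale is not shown. Those intervals take each peak as independent and hold no spread between libraries. The 2 weaker classes, left out of the test in advance, stood at 0.25 and 0.48. The values of these weaker classes can be partly set by the listing limits. Silencing of HMGB1 could give the same picture if it opened all sites in proportion. With 1 library per condition it cannot be told apart from a difference in library preparation, which would need several libraries of each line.

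The peak-free 2.36 Mb around Cdkn2a may be a deletion in the cell line, since it is shared by both libraries and covers genes of 8 families, Mtap and Klhl9 among them. Of 1020 autosomal stretches of at least 300 kb without peaks, 3 others held as many gene families, where 0 was asked for and 10 would have excluded it. Stretches over Canx, Hint1 and Rnf20, which are broadly used, also lacked peaks, so that a lack of listed peaks is not by itself a lack of DNA. The question stays open without read coverage, and no biological difference between the 2 lines was tested here, as both showed it.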
